A study of Homo sapiens with 42 samples.

How the data were processed

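H1, an established human embryonic stem cell line, was kept on matrigel in mTeSR1 medium and driven toward the neural lineage by dual-Smad inhibition, a treatment that blocks the Nodal/Activin and BMP branches of TGF-beta signalling. Chromatin was taken at 7 times (0, 3, 6, 12, 24, 48 and 72 h after the start of induction), crosslinked with formaldehyde, sheared by sonication and precipitated with an antibody against H3K27ac or against H3K27me3. H3K27ac marks active promoters and enhancers, and H3K27me3 is the mark of Polycomb repression. The labels list 42 samples: 14 libraries for each mark (2 replicates at each time) and 14 input libraries, for which no peak list exists and which were not used. The labels do not say whether the replicates were separate cultures, so every p-value here measures the spread between these samples, which may be technical only. RNA-seq, ATAC-seq and reporter assays that the design text mentions were outside the files used here.

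The deposited files were 28 peak lists, one per library, each called on its own library by the authors; the lists were narrow peaks for H3K27ac and broad peaks for H3K27me3. In each list the deposited score of a peak is a ratio, its fold enrichment over the caller's background, beside its −log10 p and −log10 q, all of them the authors' own values. Per the submitters' processing notes the tools were FastQC 0.3.2, Trimmomatic 0.3.2, Bowtie 1.1.1, Picard (no version given) and MACS2 2.1.0, with the build hg19. Their roles and options, and whether the input libraries entered the calling, are not given in the sources used here. Peak coordinates were checked against the chromosome lengths of GRCh37, which they fit. Read numbers are not part of a peak list, so the sequencing depth is unknown, and no counting interval or detection floor can be given; a window listed with no covered base may hold signal below the authors' threshold.

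Because a peak list holds presence, position and length of peaks, the quantities computed were covered bases and presence of a peak. The per-peak values of the authors served only to rank or filter peaks within a list. Peaks of each list were merged and intersected with windows around the transcription start site (TSS, the 5-prime end of the annotated gene) of 20090 protein-coding genes on chromosomes 1 to 22 and X of the GENCODE annotation for GRCh37. Each gene had 1 TSS, its outermost annotated one, so start sites farther inside a gene got no window of their own. The window reached 20 kb to each side for H3K27ac and 10 kb for H3K27me3, and a gene was tested when at least 2 libraries of the mark had a covered base in it. In genes longer than this reach, such as ACTB and LEFTY1 for H3K27ac, an inner start can lie outside the window. The log2 of the covered bases plus a prior (200 bases for H3K27ac, 500 for H3K27me3) was shifted by a per-library offset, the median difference from the gene mean over genes covered in every library (12431 genes for H3K27ac, 371 for H3K27me3). Windows of neighbouring genes share peaks. The prior shrinks changes of thinly covered windows, and the offset removes any change shared by most of those genes. limma 3.58.1 with R 4.3.3 was fitted with time as a factor of 7 levels (7 residual degrees of freedom), with eBayes and a variance trend on coverage; the contrast was 72 h against 0 h, each other time was set against 0 h as well, and an F test over the 6 contrasts asked for change at any time. The prior degrees of freedom were 5.85 for H3K27ac and infinite for H3K27me3. An H3K27me3 p-value from limma therefore uses the spread of genes of like coverage and not the gene's own. P-values were adjusted by Benjamini-Hochberg over genes with a threshold of 0.05, and adjusted p-values of genes come from this limma fit. Log2 changes are given with their SE from limma, and covered lengths as mean ± SD in kb without the offset.

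The numbers 1 and 2 of the replicates were checked for pairing by the correlation between times of the replicates' deviations from the mean of their time. All 21 pairs of times gave a positive correlation above 0.1 for H3K27ac (0.197 to 0.39, median 0.252), so the number was carried by something shared between times, and counts from a fit with replicate number as a block are printed where they differ by over 1.5 times.

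A total of 18 gene lists (293 symbols, of which 292 matched a protein-coding gene) were tested with camera at a preset correlation of 0.01, adjusted over the lists of a mark, where at least 5 members were measured: pluripotency, Nodal and Activin targets, BMP targets, neural progenitor, neuronal differentiation, mesoderm and primitive streak, endoderm, non-neural ectoderm, neural crest, trophectoderm and amnion, HOX clusters, FGF and immediate early, WNT targets, Notch pathway, retinoic acid, fibroblast markers, blood and endothelium markers, and housekeeping. Counts "adjusted over the list alone" are given beside counts over all genes tested. Named genes follow a rule: per mark the 10 highest and the 10 lowest log2 changes among genes past the threshold whose libraries at 72 h all lay on the same side of those at 0 h, at most 1 gene per 100 kb, or all that passed where fewer did; up to 4 passing members and up to 2 well-known members that did not pass from each list; and PAX6, SOX1, SOX2, POU5F1, NANOG, OTX2, LEFTY1, TBXT and ACTB. Not every gene that the rule takes is reported. These choices, the lists, the tests and most of the alternatives were set before the data were examined.

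For regions, all lists of a mark were merged where peaks overlapped, and regions held by at least 2 lists were tested for a trend with time: an exact two-sided permutation test of the rank sum of the times whose lists held the region, adjusted by Benjamini-Hochberg. The 5 gained and 5 lost regions with the smallest p are named, ties being ordered by the number of lists and then by width. Similarity of lists was measured as the base-pair Jaccard index, the shared bases as a percentage of the bases in either list, and same-time pairs were set against all assignments of the replicate 2 lists to times (exact permutation test, one-sided). Promoters (1 kb to each side of the TSS) were given a state at 0 h and 72 h where both replicates of each mark held or both lacked a peak, and are described without a test. Changes of both marks were correlated across genes on windows of 10 kb to each side; genes are not independent replicates, so no p is given. Shares of regions are given with 95% Wilson intervals, which cover counting error only. A region counted as gained by 72 h when both 72 h lists held it and neither 0 h list did, and as lost in the reverse case.

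Alternatives covered the scaling (no offset, total covered bases, quantile normalization), lists shortened to a common number of peaks by the authors' p ranking, peaks of −log10 q of at least 5, narrower and wider windows, priors 5 times larger and smaller, gene and region filters, merging distance, the replicate block, a linear trend over the order of times, the correlation in camera and leaving out each library. A false discovery rate for discrete p-values, a variance without the trend, and H3K27me3 fits without the 4 longest or without the 2 shortest lists were added after seeing the data. The limma fit was tested on simulated data with the gene means and spreads of these libraries, and the trend test on regions whose libraries were shuffled, each with planted changes. The simulated limma values had independent normal noise, with no replicate effect, no peaks shared between windows and no floor. Changes were planted only in genes outside the lowest means, so the rates of calls may not carry over to the real data. In the limma fit for H3K27ac, 28.4% of planted changes of log2 size 1, 80.6% of size 2 and 95.5% of size 3 were called, with 6 of 17166 unchanged genes; for H3K27me3 the shares were 3%, 16.4% and 40.9%, with 1 of 4276 unchanged genes. Where 200 of 80067 H3K27ac regions carried a planted full trend, Benjamini-Hochberg called 0 of them and the discrete method 200, with 6 others. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.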

Results

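The data describe how marks of active and of repressed chromatin moved across the genome while H1 human embryonic stem cells were induced toward neural fate. Both marks, H3K27ac and H3K27me3, were profiled at 0, 3, 6, 12, 24, 48 and 72 h with 2 replicates per time, giving 28 peak lists. The H3K27ac lists held 40994 to 94858 peaks covering 17.5 to 49.97 Mb. The H3K27me3 lists held 1928 to 12598 peaks covering 0.369 to 26.5 Mb. Replicate 2 covered more bases than replicate 1 at 7 of 7 times for each mark. For H3K27ac the covered length was 29.3 Mb and 40.5 Mb at 0 h and 23.5 Mb and 33.2 Mb at 72 h. For H3K27me3 it was 4.22 Mb and 5.02 Mb at 0 h and 2.01 Mb and 21.7 Mb at 72 h. The H3K27me3 lists fell into groups of unlike size. Replicate 2 at 3, 12, 48 and 72 h covered 21.7 to 26.5 Mb with median peak widths of 912 to 1116 bp. The 10 other lists covered 0.369 to 5.02 Mb with median widths of 162 to 244.5 bp. In these 10 lists the median −log10 q was 0.783 to 1.15 and the lowest 0.0839 to 0.133. The 4 long lists had medians of 2.20 to 3.94. No H3K27ac list held a peak below 1.30, but q-values of narrow and of broad peaks need not be on the same scale. Presence of an H3K27me3 peak in the 10 lists, both 0 h lists included, is therefore weaker evidence of the mark than in the 4 long lists. The depth of sequencing is unknown, since peak lists carry no read numbers.

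**Figure D1:**
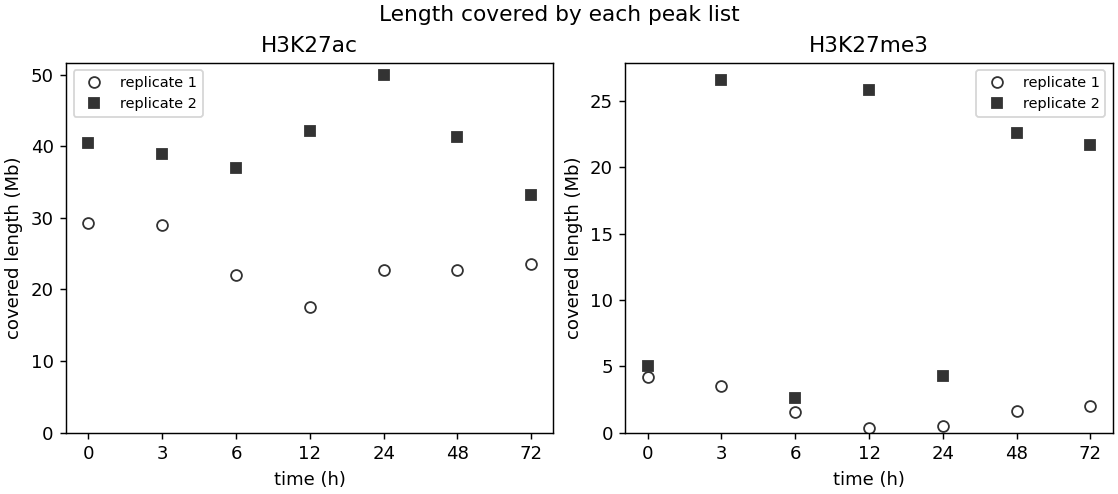
Covered length in Mb (vertical axis) of each peak list by hours after induction (horizontal axis), for H3K27ac and H3K27me3, with the replicates drawn separately. Replicate 2 lies above replicate 1 at 7 of 7 times for each mark, and 4 H3K27me3 lists of replicate 2 cover 21.7 to 26.5 Mb.

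The comparison of 72 h with 0 h asked which genes gained or lost H3K27ac around their promoters as the cells left pluripotency. The window of NANOG (chromosome 12, 7940390 to 7951742), a core transcription factor of pluripotency, had 10.8 ± 1.45 kb under H3K27ac peaks at 0 h (SD, n = 2) and no covered base in either library at 72 h (adjusted p = 1.91e-08). POU5F1 (chromosome 6, 31132114 to 31148508), which encodes OCT4, fell from 11.2 ± 2.32 to 1.08 ± 0.765 kb, a log2 change of −3.22 ± 0.24 (SE, n = 2 per time, adjusted p = 2.68e-06). In the opposite direction, the window of PAX6 (chromosome 11, 31806327 to 31839509), a determinant of neuroectoderm, rose from 0.989 ± 0.0686 to 9.33 ± 3.32 kb (log2 change 3.03 ± 0.45, n = 2, adjusted p = 0.000792). LHX5 (chromosome 12, 113899838 to 113910085), a LIM-homeobox gene of the early forebrain, rose from 1.61 ± 2.27 to 17.0 ± 1.18 kb (4.44 ± 0.96, adjusted p = 0.0115). DLK1 (chromosome 14, 101192042 to 101204561), an imprinted gene for a Notch-like membrane protein, rose from 0.236 ± 0.334 to 8.03 ± 1.36 kb (4.54 ± 0.57, adjusted p = 0.000242).

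Of 17366 windows tested with limma, 350 were higher and 827 lower at 72 h. In each of these 1177 the 72 h libraries lay apart from the 0 h libraries after the offset, as they did in 8507 of all tested windows and as chance alone would give in 33.3%. Besides LHX5 and DLK1, NR2F2, an orphan nuclear receptor of neural and mesenchymal progenitors, was among the largest gains (0.55 ± 0.151 to 12.2 ± 2.81 kb, n = 2). Others lay at RTL1 in the same imprinted locus as DLK1 (log2 change 4.04 ± 0.56), at A3GALT2 (4.12 ± 0.50) and at GREB1L (3.99 ± 0.51). No base was covered in either 0 h library at BIN2 (3.802 ± 0.347 kb at 72 h, adjusted p = 4.75e-05), AGBL1 (3.74 ± 0.65 kb, adjusted p = 0.000102), ENSG00000288658 near PAX3 (3.27 ± 0.0445 kb, adjusted p = 0.000789) and FLRT3 (3.53 ± 2.25 kb, adjusted p = 0.000298). Among the largest losses were SLC2A14 next to NANOG (log2 change −4.99 ± 0.25), the unnamed gene ENSG00000283877, whose window shares peaks with TDGF1 (−4.88 ± 0.35), and A2ML1 (−4.43 ± 0.49). So were GABRP, a subunit of a GABA receptor (−4.84 ± 0.33), and GUCY2C, an intestinal guanylate cyclase (−4.74 ± 0.42). No base was covered at 72 h at F11 (7.53 ± 0.859 kb at 0 h, adjusted p = 1.91e-08), LRLE1 (4.85 ± 2.22 kb, adjusted p = 4.95e-06), IDO2 (4.28 ± 1.25 kb, adjusted p = 9.10e-07) and GOLGA6C (8.76 ± 1.65 kb, adjusted p = 8.70e-07). GOLGA6C has near-identical copies, so its assignment is uncertain.

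The share of higher windows depended on the scaling and was 29.7% of the calls with the offset used. It was 52.3% (642 higher, 585 lower) with an offset from total covered bases, which left the median of all genes at 0.25 on the log2 scale, and 19.5% (32 and 132) without an offset. Without the offset 24 of 55 named calls passed, and PAX6, LHX5, SOX1, NR2F2, SP5, LEFTY1 and SMAD7 were among those that did not. A fit with the replicate number as a block called 646 higher and 1221 lower. A linear trend over the times called 648 higher and 774 lower (45.6% higher). The counts fell to 143 higher and 463 lower without replicate 1 at 0 h, to 117 and 508 without replicate 1 at 72 h, and to 207 higher without replicate 2 at 72 h.

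**Figure D2:**
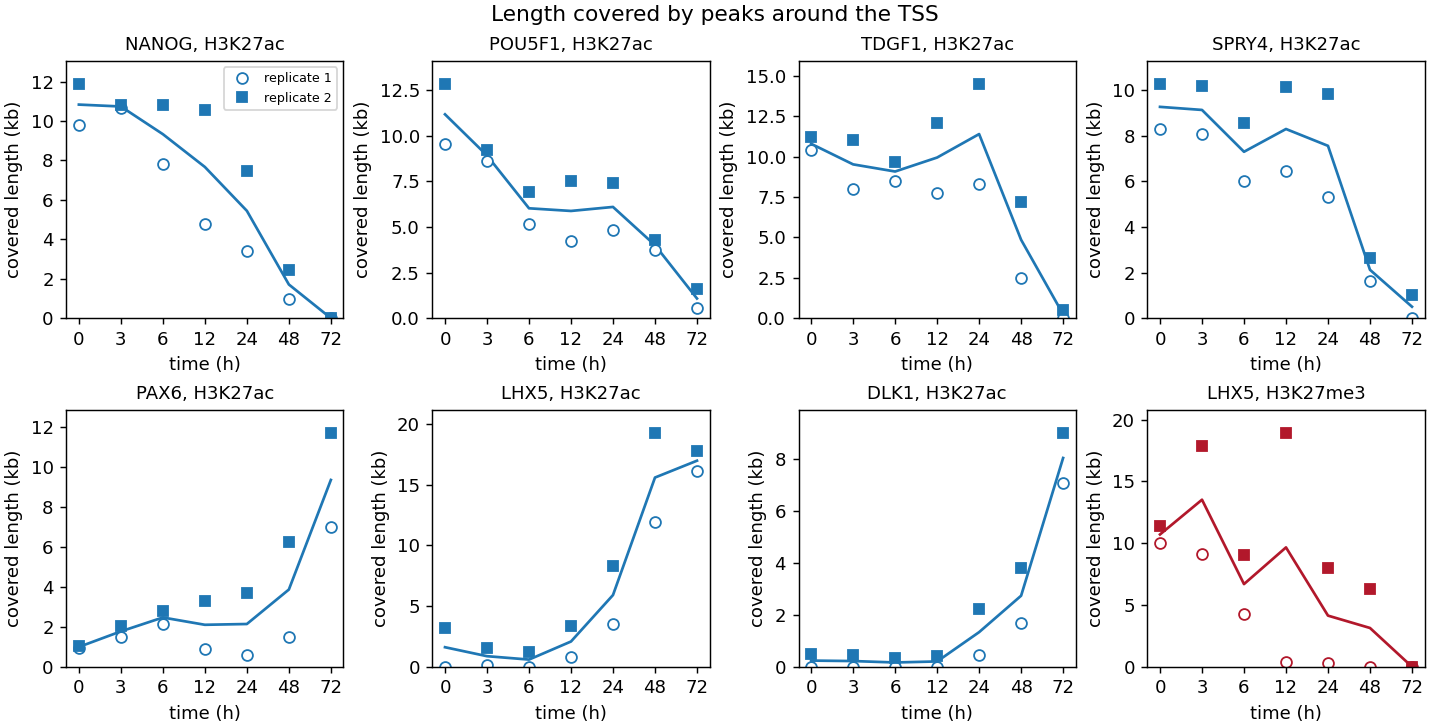
Covered length in kb (vertical axis) of gene windows against hours after induction for H3K27ac at NANOG, POU5F1, TDGF1, SPRY4, PAX6, LHX5 and DLK1 and for H3K27me3 at LHX5. Open circles are replicate 1, filled squares replicate 2 and the line their mean, and H3K27ac at NANOG falls from 10.8 kb at 0 h to 0 at 72 h, and at LHX5 it rises from 1.61 to 17.0 kb as H3K27me3 goes from 10.7 kb to 0.

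Pluripotency genes lost H3K27ac as a group. Of 20 measured members 9 fell, 1 rose and 10 did not pass (1 higher and 10 lower adjusted over the list alone), and 3 members are also in another list. Camera placed the changes of the list below those of other genes (adjusted p = 5.72e-08, and adjusted p = 0.0282 with an estimated correlation). TDGF1, a Nodal co-receptor, fell from 10.8 ± 0.552 to 0.239 ± 0.337 kb (−4.83 ± 0.34, n = 2, adjusted p = 1.89e-06), and FOXD3 from 10.1 ± 2.02 to 0.638 ± 0.298 kb (−3.59 ± 0.33). GDF3, a growth factor of pluripotent cells, had 2.83 ± 0.767 kb at 0 h and no covered base at 72 h (adjusted p = 0.00069). LIN28A, an RNA-binding protein of stem and progenitor cells, was the member that rose (8.19 ± 1.71 to 15.7 ± 2.38 kb, 0.99 ± 0.19, adjusted p = 0.00507). SOX2, which neural progenitors keep, measured 16.6 ± 4.01 kb at 0 h and 19.2 ± 2.48 kb at 72 h (0.29 ± 0.13, adjusted p = 0.265), and PRDM14 had a log2 change of −0.37 (adjusted p = 0.323).

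Targets of the signals that the treatment blocks were asked about as lists. Of 13 Nodal and Activin targets 7 fell, 1 rose and 5 did not pass (2 higher and 7 lower adjusted over the list alone), and 3 are shared with other lists. Camera placed the changes of the list below those of other genes (adjusted p = 0.000141, and adjusted p = 0.0282 with an estimated correlation). PMEPA1 (−2.94 ± 0.64), NODAL (−2.49 ± 0.63) and the inhibitor SMAD7 (11.1 ± 1.78 to 2.29 ± 0.892 kb, −2.15 ± 0.26, n = 2) fell. LEFTY1, an extracellular Nodal antagonist, fell from 4.90 ± 1.14 to 1.25 ± 0.099 kb (−1.73 ± 0.20, adjusted p = 0.000171). FST, which encodes the Activin antagonist follistatin, rose (0.75 ± 0.20, adjusted p = 0.0413). Of 13 BMP targets 2 fell, ID1 (8.81 ± 0.12 to 1.37 ± 0.838 kb, −2.57 ± 0.34) and SMAD7. The other 11 did not pass, among them ID3 (−0.39 ± 0.18, adjusted p = 0.289). Adjusted over the list alone 3 were lower, and camera did not call the list (adjusted p = 0.526), whose mean was −0.17 and median 0.05.

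Of 19 genes of FGF signalling and the immediate early response 8 fell, none rose and 11 did not pass (1 higher and 10 lower adjusted over the list alone). Camera placed the changes of the list below those of other genes (adjusted p = 1.35e-05, and adjusted p = 0.0332 with an estimated correlation). SPRY4, a feedback inhibitor of receptor tyrosine kinases, fell from 9.27 ± 1.39 to 0.502 ± 0.709 kb (−4.20 ± 0.44, n = 2, adjusted p = 6.55e-05). DUSP6 (−3.72 ± 0.81) and DUSP5 (−2.91 ± 0.45), phosphatases of MAP kinases, fell as well. ETV5, an ETS factor downstream of FGF, had 3.70 ± 1.39 kb at 0 h and none at 72 h (adjusted p = 0.000641). EGR1 did not pass (0.18 ± 0.22, adjusted p = 0.794).

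Of 34 neural progenitor genes 9 rose, none fell and 25 did not pass (15 higher and 1 lower adjusted over the list alone), and 3 are shared with other lists. Camera placed the changes of the list above those of other genes (adjusted p = 5.46e-10), but not with the correlation estimated (adjusted p = 0.127 with an estimated correlation). Besides LHX5, DLK1, NR2F2 and PAX6, SOX1, a marker of committed neuroectoderm, rose from 2.31 ± 1.02 to 9.53 ± 2.40 kb (2.06 ± 0.43, n = 2, adjusted p = 0.00897). MEIS2 (2.69 ± 0.68), IRX2 (1.67 ± 0.25) and POU3F1 (1.03 ± 0.27) rose. OTX2 (9.06 ± 3.42 and 10.9 ± 2.22 kb, 0.36 ± 0.15, adjusted p = 0.228) and SIX3 (0.84 ± 0.79, adjusted p = 0.704) did not pass.

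Of 14 WNT targets 2 rose, none fell and 12 did not pass (3 higher adjusted over the list alone). Of 14 Notch pathway genes 3 rose, none fell and 11 did not pass (4 higher adjusted over the list alone), and 2 are shared with other lists. The changes of both lists lay above those of other genes in camera (adjusted p = 0.0119 and 0.0278). Neither call held with the correlation estimated (adjusted p = 0.127 and adjusted p = 0.331 with an estimated correlation), and neither held without replicate 1 at 0 h. SP5, a direct WNT target, rose from 0.234 ± 0.0283 to 4.18 ± 0.496 kb (3.40 ± 0.69, n = 2, adjusted p = 0.00764), and SFRP1, a secreted WNT antagonist, rose by 0.99 ± 0.19. AXIN2 (0.10 ± 0.19, adjusted p = 0.878) and LEF1 (1.35 ± 0.38, adjusted p = 0.0514) did not pass. LFNG, a glycosyltransferase acting on Notch, rose from 7.11 ± 0.528 to 18.4 ± 0.356 kb (1.42 ± 0.19, adjusted p = 0.00037), beside the ligand JAG1 (1.09 ± 0.19) and the effector HES5 (0.88 ± 0.21). HES4 did not pass (1.01, adjusted p = 0.0616).

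The remaining lists were not called by camera. Of 12 neural crest genes 2 rose, 2 fell and 8 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.966). PAX3 (0.188 ± 0.266 to 2.90 ± 0.575 kb, 3.25 ± 0.63) and SOX10 (3.02 ± 0.58), genes of crest specification, rose. FOXD3 fell, and ETS1 had 3.71 ± 1.27 kb at 0 h and none at 72 h (adjusted p = 0.000768). Of 11 retinoic acid genes 2 rose, 1 fell and 8 did not pass (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.197). CYP26A1 (1.83 ± 0.43) and CYP26C1 (1.87 ± 0.41), which degrade retinoic acid, rose. Their starts (chromosome 10, 94833232 and 94820555) lie within 20 kb of each other, so the windows overlap and these are not independent gains. DHRS3 fell (−0.99 ± 0.21), after a higher level at 24 h (0.93, adjusted p = 0.0487) that passed in 5 of 13 alternatives. Of 16 non-neural ectoderm genes 1 rose (KRT19, 0.86 ± 0.22) and 2 fell, the epithelial factor GRHL2 (−0.77 ± 0.14) and TP63 (1.30 ± 0.193 kb at 0 h, none at 72 h, adjusted p = 0.0108). The other 13 did not pass, 2 were higher and 4 lower adjusted over the list alone, and camera gave adjusted p = 0.115. Of 20 neuronal differentiation genes 3 fell and 17 did not pass (2 higher and 3 lower adjusted over the list alone). Camera gave adjusted p = 0.956, pointing down as the mean (−0.21) and unlike the median (0.07). Those that fell were GAD2 (−2.99 ± 0.68), SLC17A6 (1.62 ± 1.30 kb at 0 h, none at 72 h, adjusted p = 0.0174) and SYN1 (1.30 ± 0.0403 kb at 0 h, none at 72 h, adjusted p = 0.00409). TUBB3 did not pass (0.44, adjusted p = 0.569).

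Of 17 mesoderm and primitive streak genes the VEGF receptor gene KDR fell (−1.42 ± 0.33) and 16 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.586). TBXT, the brachyury gene, measured 1.30 ± 0.397 kb at 0 h and 0.747 ± 0.677 kb at 72 h (−0.78 ± 0.65, adjusted p = 0.652). None of 7 endoderm genes passed (camera adjusted p = 0.586; SOX17 −1.37 ± 0.57, adjusted p = 0.223). Of 10 trophectoderm and amnion genes TEAD4 fell (−1.14 ± 0.18) and 9 did not pass (camera adjusted p = 0.403). None of 17 HOX genes with H3K27ac peaks passed (camera adjusted p = 0.663). Of 5 fibroblast markers THY1 fell (−1.27 ± 0.19; with windows of 50 kb to each side it was 0.18, adjusted p = 0.767) and 4 did not pass (1 higher and 1 lower adjusted over the list alone). Camera gave adjusted p = 0.877, pointing down beside a median of 0.20 and a mean of 0.04. None of 6 blood and endothelium markers passed (camera adjusted p = 0.586). None of 17 housekeeping genes passed (camera adjusted p = 0.56), among them ACTB (6.01 ± 1.29 and 4.15 ± 1.23 kb, −0.46 ± 0.13, adjusted p = 0.0581) and GAPDH (−0.09 ± 0.23, adjusted p = 0.919). The ACTB window was centred on the outermost annotated start (position 5603533), so an inner start of ACTB can lie outside it. These lists gave the same counts adjusted over the list alone, apart from the fibroblast markers. By limma 2983 of the 17366 windows had an unadjusted p below 0.05.

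When each change appeared was asked by setting every time against 0 h. Nodal targets were among the early changes. LEFTY2 was lower at 3 h (5.08 ± 0.375 to 1.45 ± 0.322 kb, −1.72 ± 0.20, n = 2, adjusted p = 0.00924) and at each later time up to 72 h (−1.70). SMAD7 was lower from 6 h on (−1.41 at 6 h, adjusted p = 0.0431). LEFTY1 (−1.31, adjusted p = 0.00746), SKIL and NANOG (−1.03, adjusted p = 0.0327) were lower at 24 h and LFNG was higher (1.38, adjusted p = 0.00303). At 48 h POU5F1 (−1.32, adjusted p = 0.00661), FOXD3 (−2.62), SPRY4 (−1.95, adjusted p = 0.0251) and ID1 (−1.86) were lower. LHX5 (4.33, adjusted p = 0.0218), DLK1 (3.01, adjusted p = 0.00877), SOX1 (2.21, adjusted p = 0.0101) and NR2F2 (3.14, adjusted p = 0.0283) were higher at that time. PAX6 and TDGF1 passed only at 72 h, with log2 changes of 1.57 (adjusted p = 0.0743) and −1.19 (adjusted p = 0.0786) at 48 h.

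Across all windows limma called 13 higher and 21 lower at 3 h, 21 and 59 at 6 h, 1 and 3 at 12 h, 160 and 91 at 24 h, and 357 and 352 at 48 h. The 12 h calls, named after their values were seen, were MYL2 (1.77 ± 0.19), and, lower, TMEM63A (−1.22 ± 0.15), LEFTY2 of the same region, and SMAD7. By the F test, H3K27ac genes changed at any time numbered 1962, and 3335 with the replicate number as a block. These contrasts share the 0 h libraries, and the 3 h call of LEFTY2 ended without either library of 0 h, without an offset, with equal lists and with the stricter q.

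**Figure D3:**
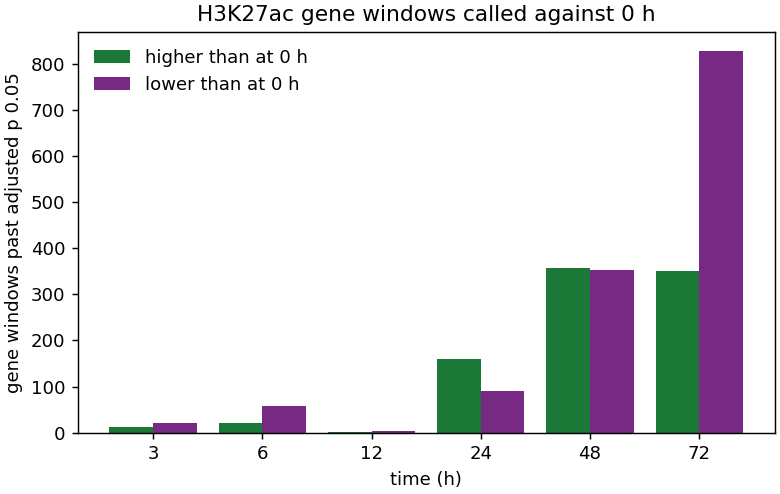
Number of gene windows (vertical axis) with higher and with lower H3K27ac than at 0 h, by hours after induction (horizontal axis), at an adjusted p below 0.05 in limma. The bars go from 13 higher and 21 lower at 3 h to 350 higher and 827 lower at 72 h, with 1 and 3 at 12 h.

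Whether H3K27ac peaks were gained or lost steadily over the course was asked region by region. The 162108 merged regions included 80067 held by at least 2 lists and 12693 held by all 14. The region on chromosome 5 from 3121018 to 3126073, between genes and 369.23 kb from IRX2, was held by 8 lists, all of late times. The same held for regions in introns of RAD51B (chromosome 14, 69053579 to 69054944) and RAB31 (chromosome 18, 9802535 to 9803580) and regions 199.98 kb from HDAC4 (chromosome 2, 240523331 to 240524952) and 58.74 kb from PODXL (chromosome 7, 131301713 to 131302999). Regions held by 8 lists of early times lay in introns of ITPR2 (chromosome 12, 26829051 to 26834725) and DSE (chromosome 6, 116643477 to 116647128), over an exon of RFTN2 (chromosome 2, 198450192 to 198454284), and 457.2 kb from PRIM2 (chromosome 6, 57636805 to 57641107) and 197.36 kb from SEMA6A (chromosome 5, 116107879 to 116111828). Each of these had an exact permutation p = 0.000666, the smallest the test can give for regions, and adjusted p = 0.0869. In all, 98 gained and 180 lost regions shared this p, and those named are the widest of those held by 8 lists. The exact permutation test with Benjamini-Hochberg called 0 regions gained and 0 lost. At an unadjusted p below 0.05 there were 10661 regions (4650 of later and 6011 of earlier times), where 1944 would arise with exchangeable libraries. The discrete false discovery rate, chosen after seeing the data, called 1099 gained and 1726 lost.

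Between 0 h and 72 h, 4248 H3K27ac regions were gained in both libraries, 8222 were lost and 18295 kept. Promoters were overlapped by 5.13% of the gained regions (218 regions, 95% CI 4.51 to 5.84), by 4.09% of the lost (3.68 to 4.54) and by 58.6% of the kept regions (57.9 to 59.3). Regions that appeared or disappeared as a whole thus lay mostly away from promoters, while a peak that only shrank counts as kept. Median widths were 621, 896 and 1756 bp, and wider regions meet a promoter more easily. The promoter share of regions that differ by replicate number was not computed. Splitting the same 4 lists by replicate number instead gave 331 and 2281 regions, and crossing times and replicates gave 613 and 650. At earlier times the gained and lost regions numbered 2678 and 3499 at 3 h, 1679 and 3874 at 6 h, 726 and 2988 at 12 h, 3390 and 3118 at 24 h, and 4210 and 5386 at 48 h. Regions held by replicate 2 alone of the same lists numbered 3041 at 3 h, 4039 at 6 h, 5981 at 12 h, 5846 at 24 h and 3911 at 48 h, so at 6, 12 and 24 h they outnumbered both the gained and the lost.

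How far the lists of a time resembled each other was asked for both marks. For H3K27ac, lists of the same time shared 43.2% of their bases against 37.1% for lists of different times (exact permutation p = 0.000198, the smallest the test can give). The similarity was highest at 72 h (51.2%, 35.7% with other times) and 3 h (49.3%), and at 12 h and 24 h (35.4% and 35.3%) it did not exceed that with other times (36.5% and 35.3%). The H3K27me3 same-time overlap was 16.6% and that of different times 15.3% (exact permutation p = 0.234). Without the 24 h pair it was 17.6% (exact permutation p = 0.0306), and measured as the share of peaks that overlap it was 54.8% against 53.4% (exact permutation p = 0.00218).

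H3K27me3 was compared between 72 h and 0 h to ask which genes lost or gained Polycomb marking. LHX5 had 10.7 ± 0.936 kb under H3K27me3 peaks at 0 h and no covered base in either library at 72 h (n = 2, adjusted p = 1.62e-18), where its H3K27ac had risen. ANKRD1, a transcriptional cofactor of muscle, fell from 6.35 ± 1.81 to 0.0395 ± 0.0559 kb (adjusted p = 9.02e-05). The Polycomb-associated gene EPOP (−2.77 ± 0.62, adjusted p = 0.00707), PRTG, a cell-surface protein of the early neural tube (−2.57 ± 0.62, adjusted p = 0.0247) and the neural homeobox gene BARHL1 (9.36 ± 1.02 to 4.40 ± 6.14 kb, −2.11 ± 0.41, adjusted p = 0.000464) fell as well. FOXD3, which had lost H3K27ac, had no H3K27me3 at 0 h and 7.72 ± 8.08 kb at 72 h (adjusted p = 0.0028). These 5 lower and 1 higher were the calls among 4476 windows tested with limma, with 170 (142 higher, 28 lower) at an unadjusted p below 0.05. Their p-values rest on a spread shared by genes of like coverage and not on the gene's own. With a variance without the trend 0 calls remained. The log2 changes stand beside an all-gene median of 0.56. BARHL1 measured 0.058 kb in replicate 1 and 8.74 kb in replicate 2 at 72 h, against 8.64 and 10.1 kb at 0 h, so in replicate 2 it lay within the 0 h range and was lower only through the offset of that long list.

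None of the 6 H3K27me3 calls held under every alternative. With no offset or with lists of equal length limma left 0 calls, and leaving out 1 library gave 0 to 5 higher and 1 to 8 lower. Without the 4 long lists, a run chosen after seeing the data that leaves 1 library at 72 h, 1 was higher and 34 lower of 2067 tested. PAX6 (−0.07), SOX1 (−0.93), OTX2 (0.21) and TBXT (0.21) did not pass (adjusted p = 0.997 each). SOX2 had no covered base at either time, and POU5F1, NANOG, LEFTY1 and ACTB were not measured. At 3, 6 and 24 h limma called 0 windows (72, 6 and 26 at an unadjusted p below 0.05) and at 48 h 7 lower. At 12 h it called 5 higher and 1 lower beside an all-gene median of 1.47. The 12 h calls, named after their values were seen, were, higher, the near-identical copies USP17L12, USP17L27, USP17L28 and USP17L29 and PRDM1 (0.37 ± 0.454 to 6.98 ± 9.88 kb). In each of these higher windows all bases covered at 12 h came from 1 library (USP17L29 measured 8.13 ± 11.5 kb). The 12 h lists covered 0.369 and 25.8 Mb. The lower one was NEUROD2 (6.31 ± 0.431 to 0.0355 ± 0.0502 kb, adjusted p = 0.000271). The F test called 23.

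The H3K27me3 change from 0 h to 72 h at neural progenitor genes and HOX clusters lay below that of other genes in camera. That contrast is with an all-gene median of 0.56 and does not by itself show a loss in these lists. Of 29 neural progenitor genes LHX5 fell and 28 did not pass, with 2 lower adjusted over the list alone and a median of −0.01 (camera adjusted p = 3.97e-11, and adjusted p = 0.185 with an estimated correlation). Of 39 HOX genes none passed, with 1 higher adjusted over the list alone and a median of −0.21 (adjusted p = 1.10e-10, and adjusted p = 0.276 with an estimated correlation). The neural progenitor call did not hold without replicate 1 at 72 h (adjusted p = 0.152). The HOX call did not hold without replicate 2 at 72 h (adjusted p = 0.691) and pointed up without the 4 long lists (adjusted p = 0.0131). Retinoic acid genes (7 measured, none passed, 1 lower adjusted over the list alone) and non-neural ectoderm genes (7 measured, none passed) had lower changes than other genes (adjusted p = 0.0014 and 0.0407). Nodal and Activin targets (6 measured, none passed) and FGF and immediate early genes (10 measured, none passed) had higher ones (adjusted p = 0.0151 and 0.0368). With an estimated correlation these gave adjusted p = 0.174, adjusted p = 0.206, adjusted p = 0.276 and adjusted p = 0.637. With it 0 of the 6 camera calls held. With quantile normalization, where the all-gene median was −0.01, the HOX and non-neural ectoderm calls did not hold. With lists of equal length the neural progenitor, non-neural ectoderm, FGF and retinoic acid calls did not hold. Without replicate 1 at 72 h the retinoic acid, non-neural ectoderm, Nodal and FGF calls ended as well (adjusted p = 0.152, 0.829, 0.11 and 0.152). Without replicate 2 at 72 h the Nodal (adjusted p = 0.186) and FGF calls (adjusted p = 0.166) ended too, without replicate 1 at 0 h the FGF call, and without replicate 2 at 0 h the non-neural ectoderm call.

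The other H3K27me3 lists were not called by camera, and except FOXD3 in the neural crest list no member passed. Adjusted p-values were 0.774 for BMP targets (10 measured), 0.33 for neuronal differentiation (16) and 0.158 for mesoderm and primitive streak (16). They were 0.948 for endoderm (9), 0.33 for neural crest (11) and 0.774 for trophectoderm and amnion (6). WNT targets (10 measured, 1 lower adjusted over the list alone) gave 0.158 and the Notch pathway (9) gave 0.945. Camera pointed down for the neuronal, mesoderm, neural crest, trophectoderm, WNT and Notch lists, whose medians were positive but below the all-gene median of 0.56. Pluripotency (4 measured, FOXD3 higher), fibroblast (2), blood and endothelium (2) and housekeeping (1) had too few measured genes to be tested.

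H3K27me3 regions were tested for a trend with time as well. The 24046 merged regions included 8862 held by at least 2 lists and 399 by all 14. The smallest exact permutation p belonged to a lost region on chromosome 5 from 3115536 to 3123160, 363.75 kb from IRX2, which overlaps the gained H3K27ac region near IRX2 (p = 0.00117, adjusted p = 1). Other lost regions lay 35.16 kb from SOX1 (chromosome 13, 112756623 to 112763551), over an exon of GREB1L (chromosome 18, 18819667 to 18825182). Further lost regions lay over an exon of DRD4 (chromosome 11, 635658 to 641134) and 375.29 kb from OR11H12 (chromosome 14, 19001240 to 19002307). A gained region lay over an exon and UTR of SMAD7 (chromosome 18, 46473598 to 46477505, exact permutation p = 0.002, adjusted p = 1). Others lay in introns of HFM1 (chromosome 1, 91852726 to 91853223) and DLG2 (chromosome 11, 85194847 to 85195348), over an exon of SAG (chromosome 2, 234234244 to 234245404) and near GADL1 (chromosome 3, 31052760 to 31056757). The test called 0 regions gained and 0 lost, with Benjamini-Hochberg and with the discrete rate. Regions with an unadjusted p below 0.05 numbered 109 (48 of later, 61 of earlier times), where 246 would arise with exchangeable libraries. Between 0 h and 72 h, 222 regions were gained, 98 lost and 1332 kept. Peaks of any listed q counted for this, and the median −log10 q was 1.15 in each 0 h list. At 72 h it was 0.783 in replicate 1 and 2.70 in replicate 2. Promoters were overlapped by 36.0% (95% CI 30.0 to 42.5), 25.5% (17.9 to 35.0) and 61.0% (58.3 to 63.5) of them. A split by replicate number gave 17 and 377 regions and a crossed split 341 and 11.

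Promoter states combined the marks to ask which promoters switched between them. Of 20090 promoters, 11714 carried H3K27ac only at 0 h and 10828 at 72 h, 276 and 258 carried H3K27me3 only, 426 and 281 both, and 5868 and 5790 neither. Another 1806 and 2933 were not assigned because the replicates differed. H3K27me3 peaks of any listed q counted, so states with this mark rest partly on weak peaks. Among the 16350 assigned at both times, 10361 stayed with H3K27ac only, 154 went from H3K27ac only to neither mark and 99 from neither mark to H3K27ac only. These directions depended on the lists. With lists of equal length 152 went to neither mark and 199 came from it, and promoters with H3K27ac only rose from 11233 to 11546. With a peak in either replicate, those with H3K27me3 only rose from 357 to 618 and those with both marks from 1111 to 2085. Promoters of POU5F1, NANOG, DPPA2, TDGF1 and GDF3 in the pluripotency list, of LEFTY1 and LEFTY2, and of ETS1 were among those going to neither mark, while 11 pluripotency promoters stayed with H3K27ac only. A state belongs to the outermost annotated start of a gene (position 31148508 for POU5F1 and 226099082 for LEFTY1). Start sites farther inside these genes were not scored. Of the HOX promoters 36 of 39 carried H3K27me3 only at both times. This rests on the full lists: with lists of equal length 1 promoter among all genes did so, against 151 with the full lists. From both marks to H3K27ac only went 12 promoters, among them CYP26A1, GREB1L, EPOP and PRTG. From H3K27me3 only to both marks went 18, among them CYP26C1, PAX3, WNT1 and NKX6-2. From H3K27ac only to both marks went 27, among them SMAD7, and to H3K27me3 only 8, among them the Nodal target PMEPA1 and NKX1-2. From H3K27me3 only to H3K27ac only went TMEM88 alone. The examples were chosen after their states were seen, apart from members of the lists, and no test was made with 2 replicates.

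Across the 4045 genes measured for both marks, the log2 changes at 72 h ran in opposite directions (Spearman rho −0.255, Pearson r −0.332, across genes, which are not independent replicates). With lists of equal length rho was −0.106 and r −0.144. With H3K27ac from replicate 1 and H3K27me3 from replicate 2 rho was −0.184, and with the reverse −0.166. The H3K27ac changes of the replicates correlated across genes (rho 0.497), and the H3K27me3 changes hardly did (rho 0.059).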

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

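The discrete false discovery rate, the variance without a trend and the H3K27me3 runs without the 4 longest or the 2 shortest lists were chosen after seeing the data. Of 55 named H3K27ac calls, 19 passed with the same sign in every run, among them NANOG, POU5F1, TDGF1, FOXD3, SPRY4, ETV5, DLK1 and GREB1L. Without an offset 24 of the 55 passed, with narrow windows 36 of 54, with −log10 q of at least 5 37, with lists of equal length 49, and with total covered bases or wide windows 53. All 55 passed with quantile normalization, with the block, without a gene filter and with the larger prior, and 46 with the smaller prior or without the variance trend. All 1177 called windows kept their sign without an offset, with total covered bases and with quantile normalization. THY1 turned to 0.18 in wide windows. Of 6 H3K27ac list calls 3 held in every run, and of 6 H3K27me3 genes and 6 H3K27me3 lists none did. Apart from the counts given here for it, the replicate block changed no call; for H3K27me3 the deviations of the replicates correlated between times from −0.009 to 0.659 (18 of 21 above 0.1), and the block gave 1 higher, 7 lower and 39 at any time. The cause was not tested for any of the changes below except where a run removed genes, peaks or libraries.

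For H3K27ac genes higher at 72 h (350) the count was 32 without an offset, 642 with total covered bases, 604 with quantile normalization, 126 with −log10 q of at least 5, 161 with narrow and 702 with wide windows, 646 with the replicate block and 648 for the linear trend. For H3K27ac genes lower at 72 h (827) it was 132 without an offset, 393 with the stricter q, 378 with narrow and 1476 with wide windows. H3K27ac genes changed at any time (1962) numbered 117 without an offset, 631 with the stricter q, 774 with narrow and 3519 with wide windows, 3335 with the block and 1216 without the variance trend. Leaving out 1 library gave 117 to 377 higher, 463 to 876 lower and 1337 to 2225 at any time, with the lone remaining library taken to vary like the others. The libraries that moved a count were replicate 1 at 0 h (143 and 463), replicate 1 at 72 h (117 and 508) and replicate 2 at 72 h (207 higher). The list count (6) was 3 with the correlation estimated and 4 to 6 with 1 library left out, where WNT and Notch were lost without replicate 1 at 0 h.

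For H3K27me3 genes higher at 72 h (1) limma gave 0 without an offset, with total covered bases, with lists of equal length, with narrow windows, with genes covered in 7 libraries or without the variance trend, 3 with quantile normalization, and 2 with wide windows, the larger prior or the linear trend. For H3K27me3 genes lower at 72 h (5) it gave 0 without an offset, with equal lists or without the variance trend, 1 with total covered bases, quantile normalization or genes covered in 7 libraries, 2 with narrow windows, 10 for the linear trend and 34 without the 4 longest lists. H3K27me3 genes changed at any time (23) numbered 0 without an offset, with equal lists or without the variance trend, 4 with total covered bases, 2 with quantile normalization, 9 with narrow and 73 with wide windows, 14 with the smaller prior, 1 with genes covered in 7 libraries, 39 with the block, 80 without the 4 longest lists and 10 without the 2 shortest. Leaving out 1 library gave 0 to 5 higher, 1 to 8 lower and 11 to 101 at any time; the higher count was 0 without either library of 0 h or replicate 2 of 72 h, 2 without replicate 1 of 24 h and 5 without replicate 1 of 72 h, the lower count was 1 without either library of 0 h and 8 without replicate 2 of 72 h, and the extremes at any time came without replicate 2 of 48 h (11) and replicate 1 of 24 h (101). The list count (6) was 3 without an offset, 2 with equal lists, 0 with the correlation estimated, 3 without the 4 longest lists, and 1 to 7 with 1 library left out (1 without replicate 1 of 72 h). Adjusted p for HOX clusters turned to 0.691 without replicate 2 of 72 h and 0.0131 without the 4 longest lists, both pointing up, and leaving out 1 library at 0 h or 72 h gave 8.67e-18 to 0.691. With equal lists it was 0.952 for FGF and immediate early and 0.275 for retinoic acid, each in the opposite direction. Fits with −log10 q of at least 5 (no gene covered in every library) and without a gene filter (no variance trend could be fitted) were not run to a value for H3K27me3.

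Trend tests called 0 regions under each alternative except the discrete rate, which called 1099 H3K27ac regions gained and 1726 lost and 0 for H3K27me3. Leaving out a time, the H3K27ac overlap was 41.8 to 44.5% and the H3K27me3 overlap 11.3 to 19.1%. As a share of peaks the H3K27me3 overlap was 54.8% (exact permutation p = 0.00218), with exact permutation p = 0.0782 for equal lists and 0.902 for the stricter q. Promoters going from neither mark to H3K27ac (99) numbered 298 when a peak in either replicate counted and 199 with equal lists, and those losing H3K27ac (154) numbered 413 with either replicate and 152 with equal lists, so that with equal lists gains outnumbered losses. The correlation of the marks (−0.255) was −0.284 with quantile normalization, −0.106 with equal lists, −0.288 with genes covered in 7 libraries, −0.161 and −0.187 with replicate 1 or replicate 2 alone, and −0.184 and −0.166 with replicates crossed. The unknown read depth limits every statement that a window holds no peak.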

Other observations

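The relabelling of libraries, the discrete rate, and the tests of the H3K27me3 list sizes and of the share of rising windows were chosen only after the result was seen. Some H3K27ac windows changed early or for a time only; these genes were chosen after their values were seen. TXNIP, a thioredoxin-binding protein regulated by glucose, rose by 3 h from 1.57 ± 0.672 to 4.998 ± 1.05 kb (SD, n = 2 per time; log2 change 1.56 ± 0.19 SE, limma adjusted p = 0.00924) and was still higher at 72 h (1.31, adjusted p = 0.000635). PLIN2, which coats lipid droplets, had 0.179 ± 0.253 kb at 0 h and 2.57 ± 0.42 kb at 6 h (3.21 ± 0.42, adjusted p = 0.0128) and did not pass at 72 h (1.12, adjusted p = 0.168). GDF15, a stress-induced cytokine, was higher at 3 h (5.11 ± 1.04 to 11.7 ± 0.854 kb, 1.14 ± 0.16, adjusted p = 0.0157) and lower at 72 h (−2.24, adjusted p = 1.89e-06). IGFBP5, an insulin-like growth factor binding protein, was lower at 3 h (−2.30 ± 0.32, adjusted p = 0.0157) and higher at 72 h (1.48, adjusted p = 0.0109). Of 13 alternatives TXNIP passed at 3 h in 8, GDF15 in 7 and IGFBP5 in 10, and PLIN2 passed at 6 h in 9 of 12; no sign changed.

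At 24 h a few windows rose that had fallen far below their starting level by 72 h. FMO4, a flavin monooxygenase gene, went from 1.89 ± 0.687 to 10.2 ± 4.6 kb at 24 h (2.32 ± 0.22, n = 2, adjusted p = 0.00039) and was lower at 72 h than at 0 h (−2.85, adjusted p = 4.42e-06). TRPM1, an ion channel gene, went from 1.89 ± 0.195 to 7.05 ± 1.88 kb (1.81 ± 0.22, adjusted p = 0.00164) and then to a log2 change of −3.31 at 72 h (adjusted p = 1.23e-06). MYL2, a myosin light chain gene, was higher at 3 h (1.21, adjusted p = 0.0232, with −0.06 as the lowest value among 13 alternatives), 6 h, 12 h and 24 h (1.18 ± 0.211 to 6.01 ± 2.33 kb at 24 h, 2.16 ± 0.19, adjusted p = 0.000214) and lower at 72 h (−2.71, adjusted p = 1.89e-06). At 24 h FMO4 passed in 12 of 13 alternatives and TRPM1 and MYL2 in 11 of 13, and all of them in 14 of 14 runs with 1 library left out. The difference between the 24 h and the 72 h contrasts was not itself tested, and replicate 2 at 24 h is the longest H3K27ac list.

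A minority of the regions that lost H3K27me3 gained H3K27ac. Of 98 H3K27me3 regions present in both libraries at 0 h and in neither at 72 h, 15.3% (15 regions, 95% Wilson CI 9.5 to 23.7) overlapped a gained H3K27ac region, 30.6% (22.4 to 40.3) a kept one and 0% (upper limit 3.77) a lost one. A loss of both marks at the same regions is thus argued against. A drop of each mark at separate places would leave no such overlap, so these shares do not address it. Among 1332 kept H3K27me3 regions the share overlapping gained H3K27ac was 6.98% (5.73 to 8.48). The kept regions are no baseline for chance, since 61.0% of them overlapped promoters against 25.5% of the lost ones. Of the gained H3K27ac regions 5.13% overlapped promoters. No control matched by location was run, so co-location by chance stays open. An exchange of the marks at single loci during induction stays a hypothesis, also because 4 of the lists differ in size. In addition, H3K27me3 peaks of any listed q counted, so a lost region may have been a weak peak at 0 h. In the reverse direction, 6.31% of 222 gained H3K27me3 regions (3.79 to 10.3) overlapped a lost H3K27ac region, no more than the 7.43% (6.14 to 8.97) of kept ones, while 0.45% (0.0796 to 2.51) overlapped a gained one, less than the 6.98% of kept ones. The gained H3K27me3 regions were narrower than the kept ones (medians 2671 and 6541.5 bp), and narrower regions overlap less. These shares therefore do not show that an exchange was absent.

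The regions that lost H3K27me3 and gained H3K27ac, listed after their values were seen, included 1 spanning the start site of ZEB2 (chromosome 2, 145268820 to 145279768), and 1 that lay 0.25 kb from EFNB1, though no 0 h list held H3K27me3 within 1 kb of either TSS. Others lay 5.23 kb from ANKRD1, 20.02 kb from DMBX1 and 74.98 kb from OTX2 (chromosome 14, 57358395 to 57363459). Farther ones lay 136.19 kb from the TSS of SOX1, 145.23 kb from that of GREB1L within its gene, and 363.74 kb from that of IRX2.

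H3K27me3 lists came in 2 sizes. The time after induction is argued against, since at 4 of 7 times the replicates fell on different sides of 10 Mb. The 10 shorter lists had shortest peaks of at most 50 bp and the 4 longer ones started at 200 bp, so a fragment length set differently in peak calling is a candidate explanation. Enrichment or sequencing depth stays open: the 4 longer lists held 2554 to 5073 peaks with a −log10 q of 5 or more and the 10 shorter ones 4 to 58, as greater depth would give, while 9 of the 10 shorter lists reached the median fold of the lowest longer list, and read numbers are not in the lists. No biological explanation besides time was tested.

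More H3K27ac windows fell than rose by 72 h, with 29.7% of the calls higher. The scaling between libraries stays open: the share was 52.3% with an offset from total covered bases, which shifts all genes alike, 38.5% with quantile normalization and 19.5% without an offset. Longer lists at 0 h are argued against as the whole cause, since with lists of equal length the share was 37.1%. A loss of H3K27ac in the cells is not excluded, as the offsets cannot separate it from a difference in yield.

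Whether chance could be excluded was asked from 100 orders of the libraries, the real one included, and the orders for calls past an adjusted p of 0.05 were drawn separately from those for the unadjusted p and the discrete rate. For H3K27ac the real order gave 10661 regions with an unadjusted p below 0.05 and the highest other 6617. Only 1 of 100 was as large, the real order itself. This argues against a chance order, though 100 orders cannot exclude it. The replicate numbers pair these libraries, so orders were drawn within a replicate number as well: 1 of 100 was as large there too, with a highest other of 6877. For H3K27ac regions past an adjusted p of 0.05 the real count was 0, as many as in 100 of 100 orders (highest other 0), and a real count of 0 cannot fall below any order. At the discrete rate the real H3K27ac count was 2825, against a highest other of 0 in free orders and 1045 within replicate numbers. For H3K27me3 the real order gave 109 regions, 39 of 100 orders gave as many and the highest other gave 1811, so chance is not excluded. These were free orders. None were drawn within a replicate number for H3K27me3, although 18 of 21 pairs of times had replicate deviations correlated above 0.1. Past an adjusted p of 0.05 the real H3K27me3 count was 0, so 100 of 100 orders of the separate draw gave as many or more. The highest other order of that draw called 2435, which points to a structure of the samples whose source was not tested.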
